A study of Brugia malayi with 3 samples.

How the data were processed

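The series holds 3 two-colour arrays of adult Brugia malayi worms. Per the labels, 30 ug of total RNA was labelled per dye after extraction with Trizol and a column clean-up, with female RNA in Cy3 and male RNA in Cy5 on every array. No array had the dyes the other way round, so no dye effect could be fitted. The scanner files of arrays 1 and 2 name the same dye for each sex in their headers. The header of array 3 names no dyes, so its direction rests on the labels, and its log ratios correlated at 0.883 and 0.887 with those of arrays 1 and 2.

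The deposited scanner files hold spot intensities at 635 nm (Cy5) and 532 nm (Cy3), foreground and local background, quantified with GenePix Pro 5.1 and not normalized, per the file headers. The share of saturated pixels per spot is a percent value made by the same software, per the file headers. The authors' deposited value table holds log2 ratios, which ran as female over male, since its columns correlated at -0.9996, -0.9995 and -0.9989 with the log2 male over female ratios from the scanner files, at slopes of -0.996, -0.999 and -0.997. Its column medians were -0.00115, 0 and 0, so the values were centred on each array, and how the authors centred them is not given in the sources used here. The table was used only as an alternative, turned to male over female and not centred further.

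Each array has 7056 probe spots, 2 for each of 3528 probes, and 624 empty spots. Gene names are those of the array files, which record the best database match of each cluster when the array was designed. The reference table at hand shares no identifier with the clusters, so no name was updated and 0 clusters were matched to it. Matches to other species' proteins name a probable relative, and probes for families of close copies, such as major sperm proteins, histones, collagens and actins, may share signal.

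Backgrounds were corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50 on median foreground and median background. Each array was then normalized by global loess, with empty spots and spots flagged by the scanner software at weight 0. Flagged spots were left out (775, 861 and 2282 probe spots flagged as not found and 176, 176 and 21 flagged as bad on arrays 1 to 3), saturated spots were kept, and the spots of a probe were averaged on the log2 scale. A probe was above background on an array if the mean foreground of a spot exceeded the median background by 2 background SDs. Probes above background in at least 1 channel on at least 2 arrays (3089) and with a value on both slides (2378) were tested. Of the 711 others, 686 had a value on slide 1 only, because many spots of slide 2 were flagged as not found. The background filter counts arrays 1 and 2, which are scans of slide 1, separately, so slide 1 alone could meet it.

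The design fixed before the data were examined took each array as 1 replicate. The depositors' design text speaks of 3 biological replicates, but the files showed that arrays 1 and 2 are scans of the same slide. Their headers carry the same labelling comment, 146 spots with a speckled background were shared by them (of 199 and 211) against 4 shared with array 3 (of 125), and 180 spots flagged as bad were the same against 1 with array 3. The scans were therefore averaged and the test ran on 2 slides, a change made after the arrays were examined, and the fit to 3 arrays, with 662 and 715 probes in place of 255 and 432, is given as an alternative. The male over female log2 ratio was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 3.84 degrees of freedom and an SD of 0.444. SDs in the text are between the 2 slides and do not include differences between the scans of slide 1.

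Where a probe was not above background in a sex on any array, or was saturated in more than 50% of its pixels on every array, the text gives a bound. The mean of the brighter sex was set against the dimmer sex's mean of, per array, the higher of the lowest signal among probes above background and the probe's own, on normalized log2 values per channel after loess and Aquantile. Such bounds hold for the mean over slides and not for each slide. They equal the measured ratio where the dimmer sex's own signal was the higher, and they are open to dye bias. Among probes higher in males, 33 had females not above background on any array and 9 were saturated in males on every array, and among probes higher in females 16 had males not above background. List medians were the same with such probes at their bounds. Where a sex was above background on only some arrays, or saturated on only some, the measured ratio is given without a bound.

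Gene lists were fixed as search words over the probe names, 24 in all, and the 20 with at least 5 tested probes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The probes named are the 10 with the largest mean ratio in each direction among those past the threshold, with the same sign on every array and an informative name and 1 probe per description, the 3 largest of any name in each direction, and up to 2 per list and direction, 69 in all, a rule fixed before the data were examined. Where a list had none past the threshold, its member with the smallest p was named. Others named were chosen after their values were seen: BMC01258, BMC03751, BMC03962, BMC12409, BMC11854, BMC03192, BMC00903, BMC10296, BMC12069, BMC05345, BMC03932, BMC06062, histones H3.3, H1 and H4, and those in the closing section.

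The fit was tested on simulated data for the comparison of males with females on 2 slides, in 20 draws over 2378 probes with 200 changed. It recovered 6.9% of 2-fold, 78.4% of 4-fold, 97.6% of 8-fold and 99.4% of 32-fold changes, and on average 6% of calls were false. The simulated errors were independent and drawn from the fit's own prior, so they hold no dye or other shared error. Only 200 probes were changed, against 28.9% of tested probes called in the data, so recovery of small changes need not carry over. When the signal of 100 probes in each channel was multiplied by 4 before normalization, the male ones shifted by 1.74 and the female ones by -2.08 on the log2 scale, where 2 was put in, and the other 2178 by 0.02. An earlier form of this test, which multiplied the male signal of 200 probes, failed its limit and was replaced; run on the same probes it gives a shift of 1.27 in place of 2. With median centring in place of loess it gives 1.83, and the test with both channels 1.95 and -1.94, so in these tests loess took up part of the male changes and slightly enlarged the female ones. Differences smaller than 2-fold were mostly beyond the reach of 2 slides, and the smallest log2 ratio called was 1.06 in size.

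Alternatives were other background corrections, normalizations, filters, tests and replicates. A variance prior with a trend and the fit to 3 arrays were added after the data were examined. Array weights and a random block for the slide were not run, as 2 slides leave no such fit. No other sample or column was left out.

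Random lists matched on brightness replaced each list member by 1 of the 20 nearest other probes in brightness. The first choice was the 100 nearest, but values set by brightness alone then landed at percentile 98.9 (with the second random seed), a false alarm. The number was lowered to 20 after the real percentiles had been seen, which gave 29.2. A second random seed was run after that, and percentiles within 2 simulation errors of a limit were then taken as undecided. Probes of mitochondrial DNA were grouped by name after their values were seen.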

Results

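Transcripts of adult males and adult females of Brugia malayi, a filarial nematode that causes lymphatic filariasis, were compared to find those that differ between the sexes. The worms had been taken from the body cavity of jirds, a rodent host, and total RNA of both sexes was hybridised together to 2-colour arrays. On each of the 3 arrays the female RNA carried Cy3 and the male RNA carried Cy5. An array held 3528 probes with 2 spots each. A probe is named here by its cluster identifier (BMC and a number) and by the database match in the array files, and 1161 probes had no match and are called unnamed.

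Arrays 1 and 2 were scans of the same slide and were counted as 1 sample, which left n = 2 slides. Their log ratios correlated at 0.996 across probes, and differences between duplicate spots on the slide correlated at 0.886 over 842 pairs, against 0.276 and 0.281 with array 3. The median foreground was 8.69 and 8.80 times the background in Cy5 and 24.99 and 16.97 times in Cy3 on the scans of slide 1. On slide 2 it was only 1.62 times in Cy5 and 3.55 times in Cy3. The number of slides limits the precision of every value. The labels do not say which worms went onto which slide, so p-values measure the spread between these 2 slides, which may be technical.

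Males exceeded females by far at 6 probes for major sperm proteins and MSP-domain proteins, the small cytoskeletal proteins that drive the crawling of nematode sperm. Females exceeded males at the probes for microfilarial sheath proteins, which coat the first-stage larvae that females carry and release. Males also had more signal at 26 of the respiration probes that match mitochondrial DNA and at 10 of 27 muscle probes, while females had more at some probes for histones, translation factors and chaperones.

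Of 2378 probes tested, 255 were higher in females and 432 were higher in males by limma with Benjamini-Hochberg adjustment, which is 28.9% of those tested. The median log2 ratio of male over female was -1.66 among probes higher in females and 2.18 among probes higher in males, a direction opposite to that of the authors' deposited value table, which runs female over male. A ratio of at least 16-fold was seen at 25 probes in females and at 124 in males. The slides' log2 ratios correlated at 0.886 across the tested probes, which are not independent replicates. No called probe had opposite signs on them, but a probe with opposite signs could not have passed, so this follows from the test. Among all tested probes, 19.7% had opposite signs. With plain background subtraction the counts were 83 and 239, and with the 3 arrays taken as 3 replicates they were 662 and 715. Every array had the same dye orientation, so a difference between sexes and a difference between dyes cannot be told apart at a single probe.

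**Figure D1:**
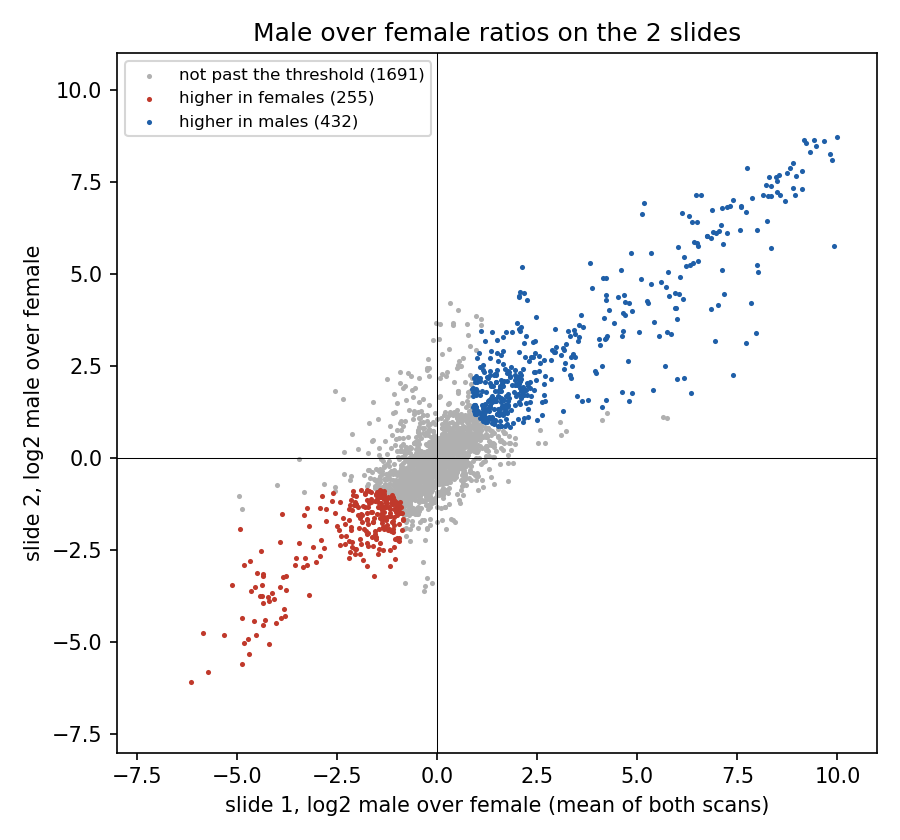
Log2 ratio of male over female for each of the 2378 tested probes on slide 1 (mean of both scans, x axis) and slide 2 (y axis). Red points are the 255 probes higher in females, blue points the 432 higher in males, grey points the 1691 not past the threshold. The called probes lie in the quadrants where both slides have the same sign, as the test requires.

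Among probes higher in males was a major sperm protein 2 probe (BMC12408), whose male signal was saturated on every array. It was at least 521-fold higher in males (measured log2 9.41 on slide 1 and 8.64 on slide 2), with an adjusted p of 0.000400. The probe for a 24 kDa secreted protein (BMC03414) was at least 217-fold higher in males (measured log2 8.48 and 7.22) and was not well above background in females on any array. Probes matching MSP-domain proteins 1 and 4 of Ascaris suum (BMC02125 and BMC10976) had log2 ratios of 7.20 ± 0.27 and 7.08 ± 0.32 (SD, n = 2). A homolog of the vespid allergen antigen, of a family of secreted nematode proteins (BMC00909), had 6.47 ± 0.94, and a protein tyrosine kinase (BMC01784) had 6.38 ± 0.38. Females were not well above background at cytochrome b561 (BMC03664, at least 45.6-fold higher in males, measured log2 6.32 and 5.25), the zinc finger protein STAT-B (BMC07636, at least 33.7-fold, 5.71 and 4.63) and a 3-keto-acyl-CoA thiolase (BMC07758, at least 23.1-fold over both slides, but 5.74 on slide 1 and 3.43 on slide 2). A protein-tyrosine phosphatase zeta precursor (BMC05756) had a log2 ratio of 5.01 ± 1.32. Unnamed probes had ratios such as 9.34 ± 0.90 at BMC03272, 9.14 ± 0.74 at BMC11964 and 9.04 ± 1.10 at BMC11914. Adjusted p values of these probes ran from 0.000400 to 0.00735. At BMC00909, BMC01784, BMC05756 and BMC11914 females were above background on only 2 of the 3 arrays. Their ratios rest partly on a signal not above background. The normalized male signal of BMC03272 was as high as that of the saturated BMC12408 (log2 16.18 and 16.17), so its ratio may also be a lower bound.

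Among named probes higher in females, a sheath protein (BMC11831) had the largest measured value, with a log2 ratio of -5.23 ± 0.50 (SD, n = 2). A high mobility group protein, a chromatin component (BMC01644), had -4.82 ± 0.13. The sheath protein SHP1 (BMC01967) had -4.50 ± 0.10 and the sheath protein precursor BMC01663 had -4.35 ± 0.07. Caveolin-1, a protein of membrane invaginations (BMC02383), had -3.97 ± 0.20. A nuclear receptor (BMC07709) was at least 9.47-fold higher in females over both slides (measured log2 -4.39 on slide 1 and -2.53 on slide 2), and males were not well above background there on any array. Glutathione S-transferase 3 (BMC01935) had -3.16 ± 0.28, histone H2A (BMC12337) -2.93 ± 0.15, a beta-mannosidase precursor (BMC02543) -2.63 ± 0.26 and methionine aminopeptidase 2 (BMC07946) -2.31 ± 0.65. The unnamed probes BMC01764, BMC02037 and BMC00257 had the largest measured values toward females, at -6.13 ± 0.05, -5.76 ± 0.06 and -5.31 ± 0.77. Adjusted p values of these probes ran from 0.000411 to 0.0111. At BMC02037, BMC01935 and BMC07946 males were above background on only 2 of the 3 arrays. Their ratios rest partly on a signal not above background. The scans of slide 1 differed at BMC01764 (-5.47 and -6.85) and at BMC01967 (-4.10 and -5.05). The small SDs of these 2 probes between slides therefore overstate their precision. Their normalized female signals were high (log2 15.5 and 15.2). Array 1 had 86 saturated Cy3 probe spots and array 2 had 0, and whether saturation affected these ratios was not tested.

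**Figure D2:**
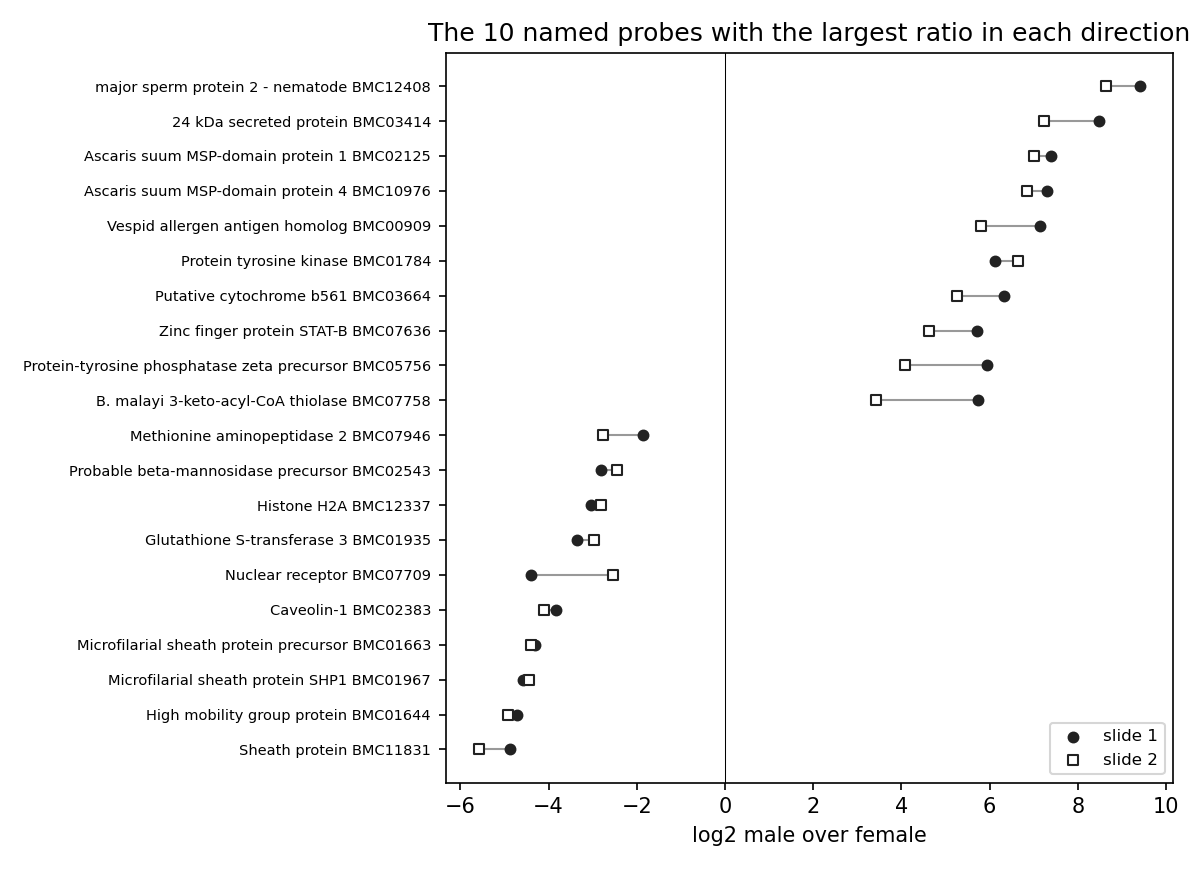
Log2 ratio of male over female on slide 1 (filled circles, mean of both scans) and slide 2 (open squares) for the 10 named probes with the largest ratio in each direction. Ratios of probes with a saturated male signal or a signal not above background in the weaker sex, such as BMC12408 and BMC07709, are measured values and not bounds. Every probe has the same sign on both slides, which the choice of probes required.

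Gene lists fixed before the data were examined describe the groups behind these probes. Of 24 lists, 20 had at least 5 tested probes, and 8 of these differed from the other probes by limma's camera with a preset correlation of 0.01 between probes. None of them passed with a correlation estimated per list, where each of the 8 had an adjusted p of 0.644.

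Sperm proteins were higher in males at 6 of 9 tested probes (7 adjusted over the list alone) and at none in females, with a median log2 ratio of 7.08 (camera adjusted p = 0.000214; adjusted p = 0.644 with an estimated correlation). The 6 were all probes for major sperm proteins or MSP-domain proteins, and they ran from 6.80 at BMC11854 to the saturated BMC12408, with 8.11 ± 1.10 at another major sperm protein 2 probe (BMC03644). Another major sperm protein probe, BMC12409, was not well above background in females on any array and did not pass (adjusted p = 0.0511). The remaining tested members are no sperm proteins, namely an egg receptor for sperm (BMC01258, log2 -0.25) and spermidine synthase, a polyamine enzyme (BMC03751, log2 -0.14), and neither passed. A further major sperm protein 2 probe (BMC03962) was above background in neither sex on any array and was not tested. Major sperm protein genes are a family of close copies, so a probe may report more than 1 of them.

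The embryo and microfilaria list was higher in females at 6 of 6 tested probes (6 adjusted over the list alone), with a median log2 ratio of -4.43 (camera adjusted p = 9.69e-05; adjusted p = 0.644 with an estimated correlation). Besides the sheath probes already named, the second sheath protein probe BMC01695 had -5.01 ± 0.44, the sheath protein SHP3A (BMC03192) had -2.06 ± 0.14 and an embryonic fatty acid-binding protein (BMC00903) had -1.57 ± 0.33.

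Mitochondrial respiration was higher in males at 28 of 71 tested probes and in females at 1 (32 and 1 adjusted over the list alone), with a median log2 ratio of 1.32 (0.82 on slide 1 and 1.51 on slide 2; camera adjusted p = 9.69e-05; adjusted p = 0.644 with an estimated correlation). Of the 28 probes, 26 matched proteins encoded in mitochondrial DNA, such as subunits of NADH dehydrogenase and cytochrome oxidase and cytochrome b. These included NADH dehydrogenase subunit 2 (BMC05800), at 3.66 ± 2.18, and cytochrome c oxidase II (BMC12069) with 2.82 ± 1.04. BMC05800 had 2.11 on slide 1 and 5.20 on slide 2, and females were above background there on only 2 of the 3 arrays. The other 2 of the 28 were cytochrome b561, a membrane electron carrier outside the respiratory chain, and adrenodoxin, an iron-sulfur protein of mitochondria (BMC10296, 1.70 ± 0.16). The 33 list members not matching mitochondrial DNA had a median log2 ratio of 0.15, a division made after the values were seen. The probe higher in females was for a mitochondrial ribosomal protein (BMC01309, -1.09 ± 0.19).

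Muscle and body wall probes were higher in males at 10 of 27 tested (11 adjusted over the list alone) and at none in females, with a median log2 ratio of 1.13 (0.54 on slide 1 and 1.37 on the weaker slide 2; camera adjusted p = 0.00257; adjusted p = 0.644 with an estimated correlation). The giant muscle protein UNC-89 (BMC06611) had 2.35 ± 1.21 and a myosin regulatory light chain (BMC03445) had 2.08 ± 0.16, and troponin, paramyosin, calponin and myosin heavy chain probes were also among the 10. The major body wall myosin probe (BMC05345) did not pass, with a log2 ratio of -0.53 and an adjusted p of 0.260. Through its search words the list as fixed also held an unconventional myosin and a myosin IXb, which need not be of muscle.

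Lists of nuclear proteins, protein synthesis and protein folding had small shifts toward females. The search words also caught other probes, such as HSPC clone names for protein folding and translationally controlled tumor protein for translation factors. Translation factors were higher in females at 6 of 27 tested probes (6 adjusted over the list alone), with a median log2 ratio of -0.43 (camera adjusted p = 0.00745; adjusted p = 0.644 with an estimated correlation). Elongation factor 1-alpha (BMC00511) had -2.25 ± 0.20 and asparaginyl-tRNA synthetase, which charges tRNA with asparagine (BMC00697), had -2.25 ± 0.30. Histones and chromatin were higher in females at 5 of 22 (2 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.0157; adjusted p = 0.644 with an estimated correlation). The 5 were the high mobility group protein and histones H2A, H3.3, H1 and H4. Protein folding was higher in females at 6 of 39 and in males at 1 (5 and 1 adjusted over the list alone), with a median of -0.43 (-0.74 on slide 1 and -0.33 on slide 2; camera adjusted p = 0.0157; adjusted p = 0.644 with an estimated correlation). The chaperones OV25-2, a small heat shock protein (BMC00498, -2.08 ± 0.98), and heat shock protein 70 (BMC12102, -2.05 ± 0.79) led it, and another small heat shock protein (BMC02059) was higher in males at 1.59 ± 0.12. With the authors' deposited values none of these 3 lists passed, with adjusted p of 0.126, 0.102 and 0.0850, translation factors did not pass with median centring either (adjusted p = 0.102), and histones did not pass when probes had to be above background in both channels on all arrays (adjusted p = 0.0658).

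Ribosomal protein probes had no settled direction. Of 104 tested, 8 were higher in females and 1 in males, and none was called in either direction when adjusted over the list alone. The median log2 ratio was -0.28 after loess normalization (camera adjusted p = 0.00364; adjusted p = 0.644 with an estimated correlation), but 0.26 with median centring and 0.42 with the authors' deposited values (adjusted p = 0.595 and 0.0850). Ribosomal proteins L5 (BMC01632, -2.05 ± 1.24) and S2 (BMC01616, -1.92 ± 0.22) were among the 8 and ribosomal protein L7a (BMC12322, 2.28 ± 0.19) was the probe higher in males.

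**Figure D3:**
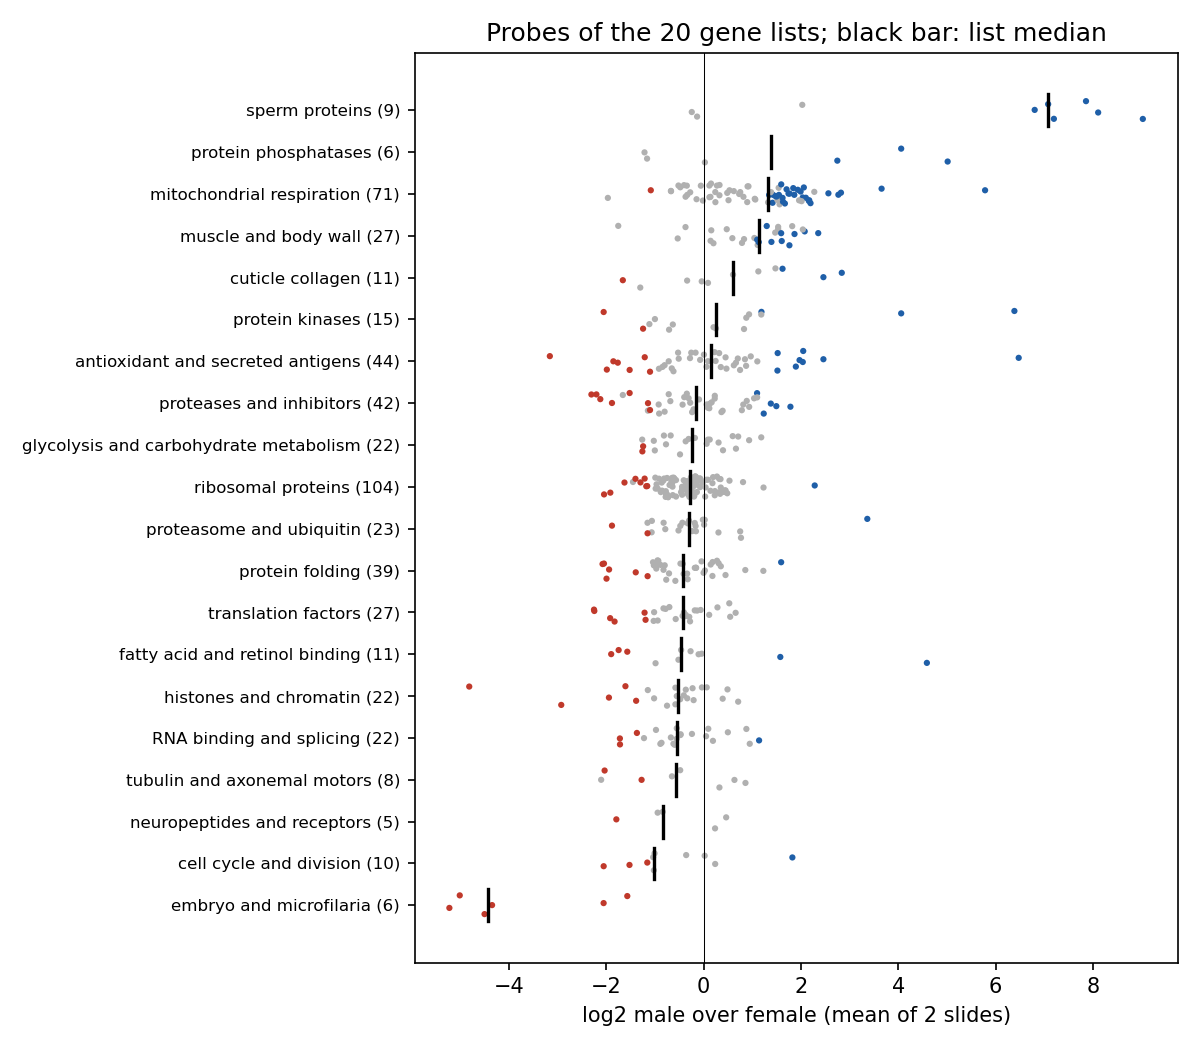
Log2 ratio of male over female (mean of the 2 slides, x axis) of every tested probe in the 20 gene lists, with the number of tested probes in parentheses and a black bar at the list median. Red points were higher in females, blue points higher in males and grey points not past the threshold, and sperm proteins at 7.08 and embryo and microfilaria at -4.43 lie at the ends, while the ribosomal median of -0.28 turned positive without loess.

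The other 12 lists did not pass camera, with adjusted p from 0.0850 to 0.763, and their called members went both ways or were few. Secreted antigens and antioxidant proteins were higher in females at 7 of 44 tested probes and in males at 8 (7 and 9 adjusted over the list alone). One of the 7 was proliferating cell nuclear antigen, which is neither and fell in the list through its name. The others toward females were led by glutathione S-transferase 3 and by macrophage migration inhibitory factor, a cytokine homolog (BMC12253, -1.99 ± 0.56), and toward males by the 5 tested vespid allergen homolog probes (BMC12291 with 2.46 ± 0.24 after BMC00909) and a transthyretin-like protein (BMC03932, 2.04 ± 0.02). Proteases and inhibitors were higher in females at 7 of 42 and in males at 5 (7 and 5 adjusted over the list alone). A cathepsin L-like protease (BMC11791, -2.21 ± 0.12) and the aspartic protease BmAsp-1 (BMC07361, 1.78 ± 0.37) were examples in each direction, and another cathepsin L-like protease (BMC04302) had 1.49 ± 0.36.

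Cell cycle proteins were higher in females at 3 of 10 and in males at 1 (5 and 1 adjusted over the list alone), and the list passed camera only with the authors' deposited values (adjusted p = 0.0340, range 0.0340 to 0.236 over 14 alternatives). Cell division protein kinase 10 (BMC09534, -2.06 ± 0.47) and cyclin B3 (BMC06324, -1.53 ± 0.70) were among the former, and DMC1, a recombinase of meiosis (BMC07925, 1.82 ± 0.20), was the probe higher in males. RNA-binding proteins were higher in females at 3 of 22 and in males at 1 (1 and 0 adjusted over the list alone), with the ribonucleoprotein Sm D3 (BMC01924, -1.72 ± 0.27), BRUNOL1 (BMC03927, -1.72 ± 0.65) and splicing factor 3B subunit 10 (BMC11804, 1.14 ± 0.07) as examples. Proteasome and ubiquitin probes were higher in females at 2 of 23 and in males at 1 (1 and 1 adjusted over the list alone), the female ones being ubiquitin isopeptidase T (BMC02903, -1.89 ± 0.13) and a ubiquitin-conjugating enzyme E2 (BMC07116, -1.15 ± 0.26) and the male one BMC12046, similar to a ubiquitin-associated protein with an SH3 domain (3.36 ± 0.13).

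Protein kinases were higher in females at 2 of 15 and in males at 3 (2 and 3 adjusted over the list alone), and protein phosphatases in males at 3 of 6 and in females at none (3 and 2 adjusted over the list alone). The stress-activated kinase JNK1 (BMC00888) had -1.25 ± 0.28. A probe for serine/threonine phosphatase 1 gamma (BMC10182) fell in both lists through its name. Females were not well above background there, and it was at least 16.7-fold higher in males over both slides (adjusted p = 0.0484), but the slides differed widely, with measured log2 ratios of 6.34 and 1.77. Cuticle collagens and cuticlins were higher in females at 1 of 11 and in males at 3 (2 and 4 adjusted over the list alone), with a cuticlin precursor (BMC06987) at -1.66 ± 0.46 and cuticle collagens at 2.84 ± 1.19 (BMC01677) and 2.46 ± 1.15 (BMC05359). Probes of the fatty acid and retinol binding list were higher in females at 3 of 11 and in males at 2 (4 and 2 adjusted over the list alone). Its search words also caught enzymes, which are no binding proteins. Among the called were the desaturase FAT-2 (BMC02897, -1.90 ± 1.20, and BMC04890, -1.75 ± 0.95) and a second 3-keto-acyl-CoA thiolase probe (BMC11647, 1.57 ± 0.38).

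Tubulins and motor proteins were higher in females at 2 of 8 (2 adjusted over the list alone), with tubulin alpha (BMC00759) at -2.04 ± 0.38 and kinesin light chain (BMC03573) at -1.28 ± 0.15. Glycolysis was higher in females at 2 of 22 (0 adjusted over the list alone), and both were probes for triosephosphate isomerase (BMC02857, -1.26 ± 0.56, and BMC11888, -1.25 ± 0.05). Neuropeptides and receptors were higher in females at 1 of 5 (1 adjusted over the list alone), the nuclear hormone receptor NHR-19 (BMC08142, -1.80 ± 0.59). These lists had no called probe higher in males.

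The remaining 4 lists had too few tested probes for camera. Of 4 tested probes for DNA replication and repair, only proliferating cell nuclear antigen, the sliding clamp of DNA polymerase, passed (BMC01736, -1.77 ± 0.29, adjusted p = 0.0150). The single eggshell probe, an endochitinase, was not well above background on any array. The Wolbachia probe, which stands for the bacterial endosymbiont of the worm, was above background in females on both scans of slide 1, in males on no array, and had no value on slide 2, so no difference between the sexes can be read from it. Of 11 probes matching rodent or host blood proteins, 1 was tested (BMC07497, log2 -0.84, adjusted p = 0.0832), and the serum albumin and immunoglobulin lambda probes were, like the Wolbachia probe, above background only in the Cy3 channel of slide 1. In that channel 17.1% and 15.5% of empty spots were above background on the scans, and a probe needed only 1 of its 2 spots. The serum albumin, immunoglobulin lambda and Wolbachia probes therefore do not show that host or Wolbachia RNA was present. BMC07497 and BMC06062, both named for mouse sequences, were above background in both channels of slide 1. BMC07497 was so in Cy3 on slide 2 as well, while BMC06062 had no value on either slide. Whether they report host RNA was not tested.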

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

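Of the tests in this part, the count of muscle probes, the count of unnamed probes, the count of arrays with swapped dyes, the second random seed and the number of nearest probes in the matched lists were chosen only after the results were seen. Empty spots, which carry no probe, gave a signal above background where none was due. Of 624 empty spots per array, 32 in Cy5 and 107 in Cy3 were above background on array 1, 39 and 97 on array 2, and 5 in Cy3 on array 3, each above the limit of 3 set for this check. The median signal of these Cy3 spots over background was 3 on array 1 and 2 on arrays 2 and 3, against 2804.5, 942 and 211.5 at the probe spots. In Cy5 it was higher, at 24.5 on array 1 and 21 on array 2 against 916 and 780 at the probe spots, so their signal is not all at the level of noise.

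The respiration and muscle lists had medians toward males, with 28 of 71 and 10 of 27 tested probes higher in males. After loess, the respiration median lay at percentile 100 and the muscle median at percentile 99.98 among 10000 random lists matched on mean brightness. Loess had already removed most of the trend with brightness, so those percentiles alone say little about it. With median centring, which leaves the trend in, they were also 100 and 99.98 (random medians 0.28 and 0.04). Mean brightness therefore does not account for either shift. Both lists had been picked for their shift, so the percentiles are no further evidence that the lists differ. Sequence-dependent labelling by the dyes cannot be told apart from sex, since 0 arrays had the dyes the other way round, and transcripts of mitochondrial DNA, which are rich in A and T in nematodes, could be labelled unequally. A larger share of muscle and other body tissue against germ line in male RNA is a candidate explanation for the 10 muscle probes higher in males, and it stays open, because only whole worms were sampled.

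Ribosomal protein probes changed direction with the normalization, from a median log2 ratio of -0.28 with loess to 0.26 with median centring. A candidate explanation is their brightness: 66 of the 104 tested ribosomal probes lie among the brightest 238 probes, which had a median log2 ratio of 0.82 on slide 1 and 0.32 on slide 2 without loess and -0.19 with it. Among random lists matched on mean brightness, the ribosomal median lay at percentile 15.7 without loess, inside the central 95%, so its positive value there is in line with a trend of bright probes. With loess it lay at percentile 2.74, and at percentile 2.49 with a second random seed, on either side of the 2.5 limit fixed for the test. That test therefore decides nothing, and a small true difference toward females stays open.

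Unnamed probes were more common among called probes, at 48.6% of those higher in males and 45.9% of those higher in females, against 31.5% of the rest. Within 10 classes of brightness the odds of being called were 1.99 times higher for unnamed probes (95% interval 1.66 to 2.39), so brightness does not account for it. Transcripts of sex-specific tissues may have weaker database matches, but among 1513 named probes the rank correlation of match score with the size of the log2 ratio was -0.0069 (permutation p = 0.789, two-sided), which decides nothing. Several probes for a shared transcript could also swell the 327 unnamed called probes, and this stays open because the probes' sequences were not analysed here.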

How the results depend on the processing

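The trended prior and the fit to 3 arrays were chosen after seeing the data. Of 54 alternative counts of probes higher in females, probes higher in males and gene lists past camera, 38 were within 1.5 times the main counts of 255, 432 and 8. No probe called in the main setting was called in the opposite direction in any of 17 settings. Probes higher in females and in males numbered 83 and 239 with plain background subtraction, which also tested fewer probes (2087). They numbered 662 and 715 with 3 arrays as 3 replicates, 64 and 185 with treat against a 2-fold change, and 70 and 202 at an adjusted p threshold of 0.01. With the plain one-sample test on 2 slides they numbered 0 and 1 (188 and 220 at an unadjusted p under 0.05). Probes higher in females fell to 166 with print-tip loess, 127 with the authors' processed values and 158 with flagged spots kept. The fit to 3 arrays counts 2 scans of the same slide as replicates, so its larger counts overstate the replication. The plain test has a single degree of freedom on 2 slides, without the prior that the main test adds. For the other shifts, apart from the stricter thresholds and fewer probes, the cause was not tested. Leaving out a scan gave 237 to 258 probes higher in females, 407 to 432 higher in males and 8 lists. Without array 3 a lone slide remains and no test is possible, and all 69 named probes kept their sign. For called probes that sign was fixed by the main test. Males made up 62.9% of calls, but 74.2% with background subtraction and 51.9% with 3 arrays. Gene lists past camera numbered 5 with the authors' processed values, among them cell cycle, which is not one of the 8, and 0 with an estimated correlation and with fry. Camera with an estimated correlation could hardly pass on 2 slides. Ribosomal proteins reversed to 0.26 with median centring and 0.42 with the authors' values (adjusted p = 0.595 and 0.0850, range 0.000211 to 0.595 over 14 alternatives). The embryo, respiration, sperm and muscle lists passed in all 14. Of 1210 values of named probes under alternatives, 995 were unchanged (in sign alone for the 69 without array 3), 213 lost the call, 2 gained it and 0 reversed. No filter on dim probes and Aquantile scaling changed nothing and so tested nothing. The random slide block and array weights were not run. The main test is already paired, since each array's ratio sets a male against a female sample. Low signal over background on slide 2 limits dim probes.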

Other observations

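Probes for transcripts of mitochondrial DNA moved together toward males. Over 42 probes matching ATPase subunit 6, cytochrome b, cytochrome oxidase subunits and NADH dehydrogenase subunits, 30 were higher in males by limma with Benjamini-Hochberg adjustment, 0 were higher in females, and 41 had a log2 ratio above 0 on both slides. The called ones ran from 1.34 to 3.66, the highest at a probe with females above background on only 2 of the 3 arrays (BMC05800). The median was 1.24 on slide 1 and 2.29 on slide 2, and 2.36 over both slides with median centring in place of loess. The exception was a cytochrome oxidase subunit 1 probe (BMC00340) with -0.34 on slide 1 and -3.60 on slide 2. The other members of the respiration list had a median of 0.15, with 2 of 33 higher in males and 1 higher in females. They are a mixed set caught by the search words, with vacuolar ATP synthase and mitochondrial ribosomal probes among them. Nuclear subunits of the respiratory chain were not analysed as a group. The 6 tested probes with the word nadh-ubiquinone in their name, which lie outside the mitochondrial DNA group, had a median of 0.28. Of these, 0 were higher in females and 0 in males. The group was formed after the values were seen, and these probes stand for few transcripts of a shared genome and are not independent.

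The 5 tested probes for vespid allergen homologs were all higher in males, from 1.89 (BMC00351) to 6.47 (BMC00909), with 4 of them between 1.89 and 2.46. A scan of 65 words in the informative names, chosen after the data were seen, gave an adjusted p of 0.00125 for the word vespid among probes higher in males (one-sided Fisher's exact test, 130 tests). The test takes probes as independent, which probes that share a description are not, so the p values of these words are too small. Other words past 0.05 in males were nadh, cytochrome, oxidase, allergen, dehydrogenase, atpase and antigen. They are not separate groups, since they share probes. The 13 called probes with the word dehydrogenase are those with nadh, and the 5 called with allergen or antigen are the vespid allergen probes. Cytochrome and oxidase share the cytochrome oxidase probes, and the called atpase probes include those for mitochondrial ATPase subunit 6. The word sheath was the only word past it in females, at 5 of 5 probes (adjusted p = 0.000319). Words for zinc finger proteins came close without passing (4 of 6 probes with the word finger, adjusted p = 0.0554), led by STAT-B and by an IgG-immunoreactive zinc finger protein (BMC06355, log2 3.60).

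Members of some families went opposite ways. Cathepsin probes were higher in females at BMC11791 (-2.21) and BMC02319 (-2.13) and higher in males at BMC04302 (1.49) and BMC00098 (1.38), and the others did not pass. Among tested probes named for macrophage migration inhibitory factor, BMC12253 and BMC12254 were higher in females (-1.99 and -1.86) and factor 2 (BMC02968) did not pass (0.85), while a probe named for the genomic MIF-1 locus (BMC06334) was higher in males (1.51) and other probes for that locus did not pass. Small heat shock proteins had BMC03771 at -2.00 and BMC02059 at 1.59. That was the only description of 124 shared by several tested probes with calls both ways, and over the 320 probes with such descriptions the intraclass correlation of log2 ratios was 0.693 (permutation p = 0.0005, the smallest that 2000 permutations can give).

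Of the 686 probes measured only on slide 1, 28 had at least 4-fold more signal in males and 15 at least 4-fold more in females, with no replicate.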
